A study of Caenorhabditis elegans with 4 samples.

How the data were processed

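The series is a chromatin immunoprecipitation sequencing (ChIP-seq) study of ELT-1 in Caenorhabditis elegans. Per the labels, hermaphrodites of strain OP354 carried an elt-1 transgene with an EGFP tag and an unc-119 rescue marker. They were grown at 20 °C to the L2 larval stage and crosslinked with 2% formaldehyde, and sheared chromatin was precipitated with goat anti-GFP antibodies. The labels name 2 ChIP samples and 2 input samples (total chromatin DNA of the same kind of extract). Samples were grouped by their titles. The free-text description of the ChIP samples reads as input and that of the inputs names the antibody, so the description field contradicts the titles and source names and was not used.

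The 3 files used are lists of called regions, 1 for each ChIP sample and 1 named as combined. Input files and read counts were not analysed here. Regions were called with PeakSeq, a program that scores stretches of tags in a ChIP library against a control, and coordinates are on WormBase release WS180, per the file headers and source column. Each region has a start, an end and a q-value. The deposited q-value is the authors' own value for that region. It depends on library depth, so it was used to rank and describe regions within a list. Between lists it was compared by rank correlation, by Pearson correlation of q and of log10 q, by counts of equal, lower and higher values, and by the size of differences in −log10 q, none of which tests a difference in binding. The PeakSeq version, the aligner, the read filters, the control used for each call, the q-value threshold and the way the combined list was made are not given in the sources used here. The number of reads behind each list is therefore unknown, and no interval that needs read depth is given. The largest deposited q-value was 0.000112 in the replicate 1 list and 0.000122 in the replicate 2 and combined lists.

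Regions of 2 lists were counted as shared when they overlapped by at least 1 bp. Overlap counts were tested against 10000 circular shifts of one list along each chromosome (one-sided permutation test, smallest possible p 1e-04). Agreement of q-values over shared regions was tested with 100000 permutations (two-sided, smallest possible p 1e-05), and so was the difference in median −log10 q between shared and unshared regions. Chromosome shares were tested with two-sided exact binomial tests, adjusted by Benjamini-Hochberg over the 6 chromosomes, and with 100000 Monte Carlo draws over all chromosomes. The share of region centres in the middle 33.3% of each chromosome was tested with a two-sided exact binomial test. Regions with a neighbour whose nearest edge lay within 2000 bp were counted and set against 10000 uniform random placements per chromosome. Intervals on shares are 95% Clopper-Pearson intervals and treat regions as independent, which grouped regions are not. Chromosome lengths of WS180 are not in the lists, so the largest region end over the 3 lists stood for the length of each chromosome, 99.4 Mb in total. Tests across regions take regions, not animals, as the unit. There are only 2 ChIP replicates, and the labels do not say whether they came from separate cultures, so no p-value here measures the spread between cultures.

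The rule for named regions was set before the data were examined: the 15 highest-ranked combined regions that overlap a region in both replicate lists. Alternatives set then were a reciprocal overlap of 50%, region centres within 200 bp, the stronger 50% of each list, lists cut to equal length, each replicate list alone, regions found in both lists, and other distances. Several more, such as merging nearby regions, were added after the data had been seen. Planned tests of gene features, distances to gene starts, 12 gene lists, the GATA motif and the elt-1 and unc-119 loci were not run. They need a genome or annotation on WS180, and the only gene table used here is on assembly WBcel235. That table served for the chromosome of a gene and the number of protein-coding genes per chromosome. No region was assigned to a gene, and no coordinate was converted.

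The tests were tried on 100 simulated pairs of lists with the real list sizes of 251 and 470 regions. The overlap test called 2% of unrelated pairs and 100% of pairs in which 50% of regions were planted, and it recovered 49.9% overlap. The grouping test called 2% of random lists and the X-share test 3%. Regions in these lists were placed independently, so the 3% does not apply to grouped regions such as the real ones. In the same simulations, with planted regions moved by a random offset, 2.34 edges per pair coincided to the base, against 2.43 edges at each other offset up to 10 bp. That near equality is built into the simulation. It checks the counting and does not show how often edges called from separate libraries coincide. In a further 400 simulations without an effect, the correlation test called 5% and the median test 6.5%. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.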

Results

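Binding of ELT-1, a GATA-type zinc finger transcription factor known for specifying epidermal cells, was mapped by ChIP-seq in L2 larvae that carried a GFP-tagged copy of the protein. The measurements are 3 lists of PeakSeq regions on WormBase WS180, 1 for each of the 2 ChIP replicates and 1 combined list. Replicate 1 had 251 regions covering 106 kb, replicate 2 had 470 regions covering 203 kb, and the combined list had 470 regions covering 203 kb. The median region width was 347 bp in replicate 1 and 358 bp in both other lists. Most regions were narrow, and 9 combined regions were wider than 1000 bp. The median −log10 q was 5.92 in replicate 1, 5.88 in replicate 2 and 5.86 in the combined list.

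**Figure D1:**
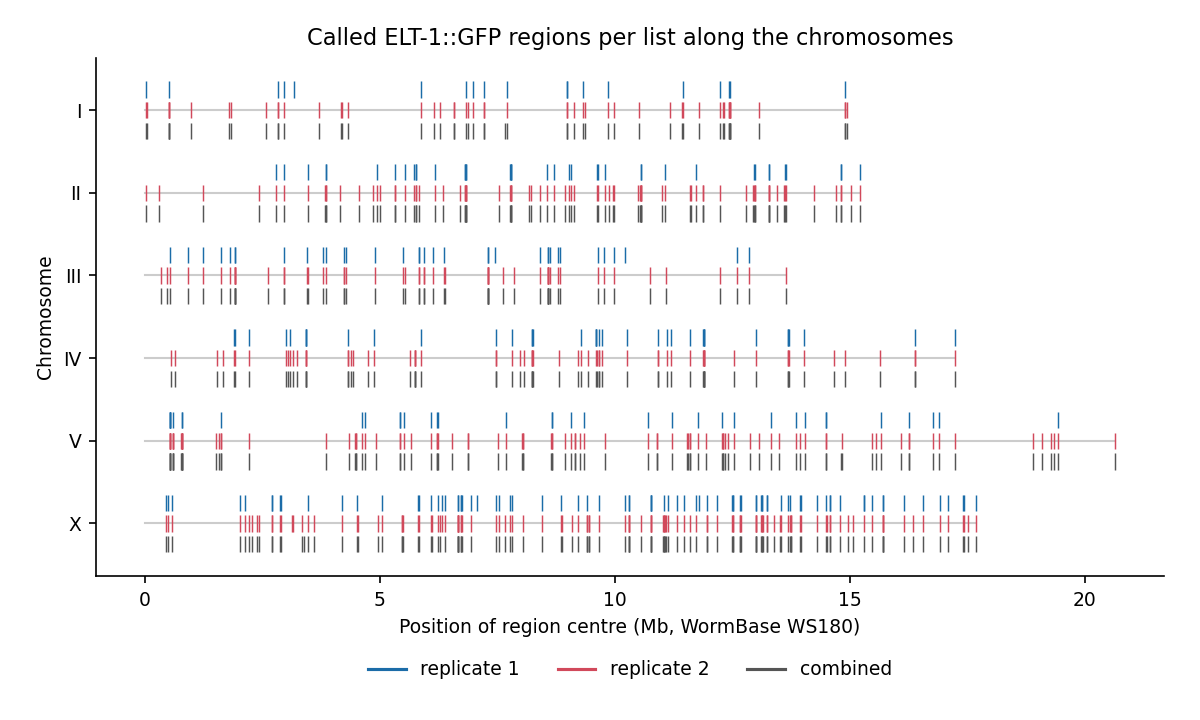
Centres of called regions along each chromosome (x axis, Mb on WS180; y axis, chromosome), with 1 tick per region in the replicate 1, replicate 2 and combined lists. The combined list follows the replicate 2 list nearly tick by tick (467 of 470 regions overlap), and the X chromosome holds 123 of the 470 combined regions.

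The strongest region of all 3 lists lay on chromosome IV, from 9612715 to 9620283. It was 7569 bp wide, 21.1 times the median width, with a q-value of 5.02e-194 in the combined list, 1.69e-146 in replicate 1 and 5.02e-194 in replicate 2. A further region of 5812 bp lay 276 bp to its left, from 9606627 to 9612438, with a combined q-value of 7.20e-13. Together they spanned 13.7 kb, and the next called region was 49.7 kb away. Replicate 1 had 3 regions in the same stretch, of which the widest was 6201 bp. The next widest combined region elsewhere, at 2453 bp, was on chromosome V. The WBcel235 gene table lists elt-1 itself on chromosome IV and unc-119, the transformation marker, on chromosome III. Both genes are also present on the transgene. Whether the strongest region lies at elt-1 was not tested, because region and gene coordinates are on different builds. The strongest region is therefore not shown to reflect ELT-1 binding apart from the transgene.

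After this region, the strongest sites found in both replicate lists were spread over all 6 chromosomes. On chromosome IV, the region from 1911128 to 1911847 had a q-value of 1.97e-58 in the combined list and 2.34e-40 in replicate 1. On chromosome V, the region from 14506520 to 14507193 had a q-value of 2.75e-53 in the combined list and 7.05e-36 in replicate 1. A wider chromosome V region, from 19428048 to 19430500, had q-values of 2.31e-52 and 2.21e-36 in these lists. On chromosome I, the region from 8985556 to 8986316 had q-values of 2.17e-40 and 1.25e-20. The other 3 regions on chromosome V were among the 15 named, from 801514 to 802612, from 15660936 to 15661391 and from 5425031 to 5425538. Chromosome II gave the region from 15213628 to 15214096 with a combined q-value of 3.89e-32, and chromosome III the region from 5838260 to 5838992 with 2.21e-28. The 5 on X started at 6091946, 12511228, 12515736, 6743572 and 8857997 and ended at 6092880, 12511732, 12516391, 6744300 and 8858901. The strongest of them, the first, had q-values of 2.41e-30 in the combined list and 8.21e-21 in replicate 1. All 15 ranked within the first 15 of the combined list and the first 20 of replicate 1, and all 15 had a lower q-value in replicate 2 than in replicate 1.

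The replicate lists were compared to see which sites recurred. Of the 251 replicate 1 regions, 245 (97.6%, interval 94.9 to 99.1) overlapped a replicate 2 region, against a mean of 1.09 after circular shifts (one-sided permutation p = 1e-04, the smallest the shifts can give). In the other direction 244 of 470 replicate 2 regions (51.9%, interval 47.3 to 56.5) overlapped a replicate 1 region, against a mean of 1.09 (permutation p = 1e-04). With the replicate 2 list cut to its 251 strongest regions, 206 replicate 1 regions (82.1%) were overlapped, and 205 of those 251 replicate 2 regions (81.7%) overlapped a replicate 1 region. The 6 replicate 1 regions without a partner lay on chromosomes I, III and X. The strongest of them, on chromosome I from 3171487 to 3172050, ranked 71 of 251 with a q-value of 9.98e-09. The files do not settle whether the 2 lists come from separate reads, and 41 region edges coincided to the base between them.

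Replicate 2 regions shared with replicate 1 were the stronger ones. Their median −log10 q was 8.96, against 4.81 for the 226 unshared regions (difference 4.15, permutation p = 1e-05, the smallest the permutations can give). Of the strongest replicate 2 regions, ranks 1 to 117, 97.4% (interval 92.7 to 99.5) were shared. The share was 69.5% (60.3 to 77.6) for ranks 118 to 235, 29.9% (21.8 to 39.1) for ranks 236 to 352 and 11.02% (6.00 to 18.1) for ranks 353 to 470. The files do not settle whether the replicate 2 list was called on reads that include those of replicate 1. If it was, the lists are partly compared with themselves. The difference and the fall along the ranks are therefore not shown to measure reproducibility. In the replicate 1 list, shared regions had a median −log10 q of 5.97 and the 6 unshared ones 4.36, a difference that did not pass the test (permutation p = 0.201).

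Over the 245 shared pairs, strong regions in one list were strong in the other, with Spearman's rho of 0.862 (permutation p = 1e-05). This is a correlation across regions, which are not independent replicates. If the replicate 2 list was called on reads that include those of replicate 1, which the files do not settle, the lists are partly compared with themselves. The correlations here are therefore not shown to measure reproducibility between replicates. Pearson's r was 0.986 on the log10 scale and 0.957 without the 2 regions farthest from the replicate 1 median. On the q-values as deposited it was 0.309 (permutation p = 7.00e-05), where the weakest regions set the scale. The q-value was lower in replicate 2 for 238 of the 245 pairs, and the median difference in −log10 q was 2.95. These 4 correlations were one family on the same pairs, with Benjamini-Hochberg adjusted permutation p of 7.00e-05 for the untransformed q-values and 1.33e-05 for the other 3.

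**Figure D2:**
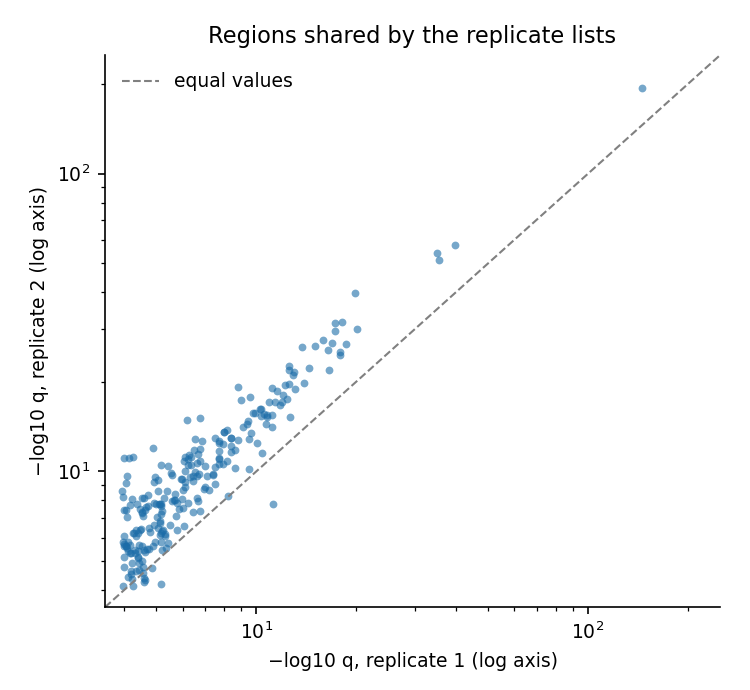
The −log10 q of the 245 shared regions in replicate 1 (x axis) and replicate 2 (y axis), both on log axes, with 1 point per region and the dashed line at equal values. Points lie above the line for 238 regions, which had the lower q-value in replicate 2.

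The combined list was compared with both replicate lists. Of its 470 regions, 467 (99.4%, interval 98.1 to 99.9) overlapped a replicate 2 region and 243 (51.7%, interval 47.1 to 56.3) a replicate 1 region. In 341 regions (72.6%, interval 68.3 to 76.5) the start and end were the same to the base as in replicate 2, and all 341 also had the same q-value. Only 6 combined regions (1.28%) had the start and end of a replicate 1 region. Equal q-values occurred at 401 regions overlapping replicate 2 and at 0 regions overlapping replicate 1. The q-value was lower in the combined list than in replicate 2 at 34 regions and higher at 32. For the 243 regions found in all 3 lists it was lower in the combined list at 17 (6.996%, interval 4.13 to 10.96), higher at 20 and equal at 206. The 3 combined regions absent from replicate 2 were weak, the strongest with a q-value of 8.76e-05. No test was made of these shares, because the combined list repeats regions and q-values of replicate 2.

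Edges of the 245 shared pairs of replicate regions were compared base by base. In total 19 starts and 22 ends, or 41 edges, were the same in both lists. Other offsets of up to 10 bp held 5.50 edges each on average and 11 at most (one-sided exact binomial p = 5.36e-20). This test was added after the data had been seen. It takes edges as independent and evenly spread over the offsets up to 10 bp. Edges called from separate libraries at the same sites need not be so, and the p-value does not tell separate from shared reads. Both edges were the same in 5 pairs, against 1.71 for independent edges. Of the replicate 1 regions, 176 (71.8%) lay wholly within the overlapping replicate 2 region.

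**Figure D3:**
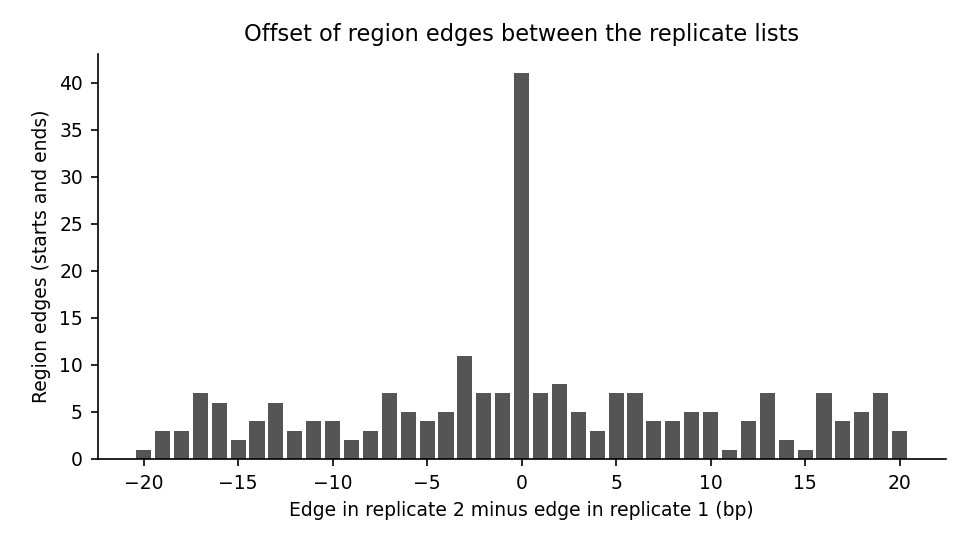
Number of region edges, starts and ends together (y axis), by the distance in bp from the edge in replicate 1 to the edge in replicate 2 (x axis), over 245 shared pairs. The bar at 0 bp holds 41 edges, and no other offset up to 10 bp holds more than 11.

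ELT-1 regions were more frequent on the X chromosome than its length predicts. X held 123 of the 470 combined regions (26.2%, interval 22.3 to 30.4) and 17.8% of the chromosome length, a ratio of 1.47 (exact binomial adjusted p = 4.31e-05). In replicate 1 the share on X was 33.1% (interval 27.3 to 39.3, exact binomial adjusted p = 4.01e-08), and in replicate 2 it was 26.6% (22.7 to 30.8, adjusted p = 1.33e-05). Chromosome I held fewer regions than its 15.04% of length, with 11.1% of the combined list (exact binomial adjusted p = 0.0425) and 7.57% of replicate 1 (adjusted p = 0.00157). Chromosome V held 14.3% of replicate 1 regions for 20.8% of length (exact binomial adjusted p = 0.0205), and 19.8% of combined regions (adjusted p = 0.649). Chromosomes II, III and IV did not pass the exact binomial test in any list. The shares of a list add up to the whole, so an excess on X by itself lowers the shares of the autosomes. Whether chromosomes I and V held fewer regions apart from that was not tested. The density on X was 6.96 regions per Mb in the combined list and ranged from 3.48 on chromosome I to 5.32 on chromosome II over the autosomes. Over all chromosomes the combined counts departed from the length shares (Monte Carlo permutation p = 3.00e-05).

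**Figure D4:**
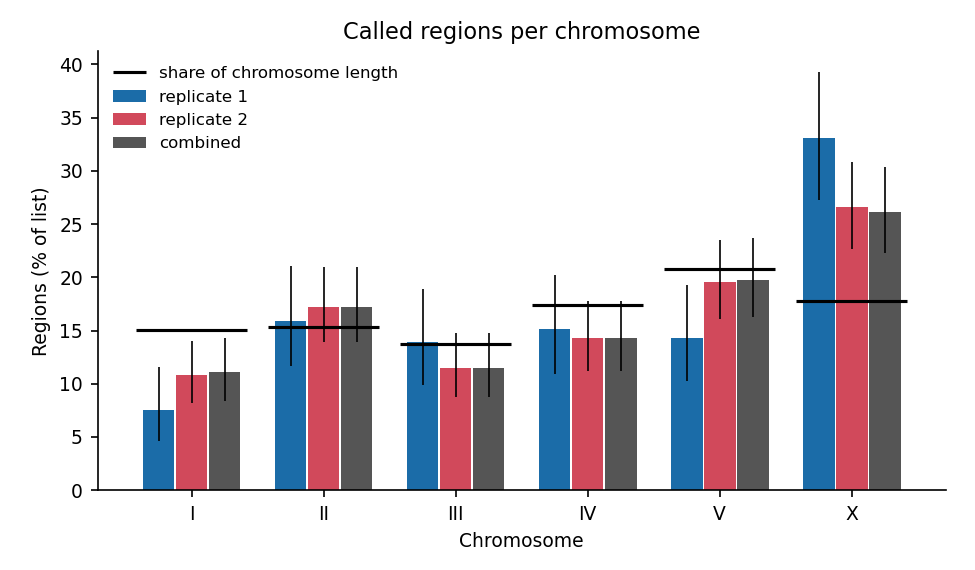
Share of called regions on each chromosome (y axis, % of the list; x axis, chromosome) for the 3 lists, with 95% Clopper-Pearson intervals as error bars and black lines at the chromosome's share of length. X lies above its length line in each list, at 33.1%, 26.6% and 26.2%.

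Taken over all chromosomes, regions were more frequent in the middle part, but no single chromosome's interval excluded 33.3%. The middle 33.3% of the chromosomes held 186 of 470 combined region centres (39.6%, interval 35.1 to 44.2, exact binomial p = 0.00452) and 105 of 251 in replicate 1 (41.8%, interval 35.7 to 48.2, exact binomial p = 0.00489). On the autosomes alone the share was 40.1% (exact binomial p = 0.00876). On X it was 38.2% (interval 29.6 to 47.4, exact binomial p = 0.252), and X had 27 regions in the left part, 47 in the middle and 49 in the right part. In the same order, chromosome I had 16, 18 and 18 regions, II had 15, 35 and 31, III had 21, 24 and 9, IV had 22, 27 and 18, and V had 36, 35 and 22. With combined regions within 10000 bp joined, the middle 33.3% held 138 of 356 loci (38.8%, interval 33.7 to 44.0, exact binomial p = 0.0326).

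Regions occurred in groups. In the combined list 110 of 470 regions (23.4%, interval 19.6 to 27.5) had another within 2000 bp, against 11.2 in random placements (one-sided permutation p = 1e-04, the smallest the placements can give). In replicate 1 alone the share was lower, with 36 of 251 regions (14.3%, interval 10.3 to 19.3) against 3.53 in random placements (permutation p = 1e-04). Joining combined regions within 10000 bp gave 356 loci, of which 283 held a single region and 73 held more. The most regions in a locus was 5, on chromosome I from 12438596 to 12453402 and on chromosome II from 6821068 to 6843124. A chromosome V locus from 538405 to 542908 held 4 combined regions within 4.50 kb, and all 4 positions were also called in replicate 1.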

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

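Across 13 results and 56 alternatives, 46 of them set before the data were examined, no result changed direction, and 43 of the 44 alternatives with a test stayed on their side of the threshold of 0.05. The exception was the share in the middle 33.3% on X alone, 38.2% (exact binomial p = 0.252), which rests on fewer regions. The tally overstates robustness, because several alternatives could hardly come out otherwise. The replicate 2 list nearly repeats the combined list, and both had 186 of 470 centres in the middle 33.3% and 110 of 470 regions with a neighbour. Uniform random placement leaves the observed overlap unchanged. Every overlap alternative between the replicate lists had a permutation p of 1e-04, the smallest the shifts can give. The share of replicate 2 regions overlapped by replicate 1 rose from 51.9% to 81.7% with lists cut to equal length (permutation p = 1e-04), which leaves out the weaker replicate 2 regions. Of the values with no test, the share of replicate 1 regions overlapped by the combined list moved beyond its interval, from 97.2% to 92.8% with a reciprocal overlap of 50% and to 99.2% in the stronger 50% of each list. The fewer pairs that qualify under the stricter overlap give the first; the cause of the second was not tested. The share of regions with a neighbour within 2000 bp was 14.3% in replicate 1 alone, 23.4% in replicate 2 alone, 13.6% in regions found in both lists and 15.3% in the stronger 50%. Shorter lists also had fewer neighbours in random placements. Replicate 1 had 36 against a mean of 3.53, regions found in both lists 33 against 3.37 and the stronger 50% 36 against 2.97. The combined list had 110 against 11.2. Observed counts and random means fell together, so the lower shares do not show weaker grouping. No test compared the lists. The share was 13.2% after joining regions within 1000 bp, which removes the closest neighbours. It was 5.11% for a limit of 500 bp and 39.8% for 10000 bp. The share on X ranged from 26.2% to 33.1%, and the share in the middle 33.3% of chromosomes from 38.2% to 46.0%. With each replicate list alone, X held 33.1% and 26.6%. Using the largest end times (n + 1)/n as chromosome length gave an exact binomial p of 5.14e-06 for X, against 7.19e-06. No paired analysis was possible because only the ChIP samples have region lists here and the input samples have no values to pair with them. The planned tests of gene features, distance to gene starts, gene lists, the GATA motif, motif and strength, and the elt-1 and unc-119 loci were not run for want of a WS180 genome or annotation. Read depth is unknown, so a region called in one list and missing from another is not shown to be unbound there.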

Other observations

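Each test in this part was chosen, or turned into a test of an explanation, only after the data had been seen. The share on X in the stronger 50% of the combined list and the grouping in replicate 1 alone had been set as alternatives before. The joining of regions within 1000 bp, at both limits, was added after the data had been seen, with each expected outcome written before its own result. Among replicate 2 regions, those shared with replicate 1 lay on X more often than the unshared ones. X held 80 of 244 shared regions (32.8%, interval 26.9 to 39.1) and 45 of 226 unshared regions (19.9%, interval 14.9 to 25.7), with an odds ratio of 1.96 (two-sided Fisher's exact p = 0.00172). Within 4 equal parts of the replicate 2 ranking, 70.2 shared X regions were expected for the 80 seen (two-sided permutation p = 0.00628). The parts match strength only roughly, since the first ran from a q-value of 5.02e-194 to 2.90e-10. A remaining difference in strength within the parts is therefore not excluded. X regions themselves had a median −log10 q of 6.36 in the combined list and autosomal ones 5.64, a difference that did not pass the test (permutation p = 0.0519; 0.267 in replicate 1 and 0.120 in replicate 2).

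The first pattern is that the combined list nearly repeats the replicate 2 list. Adding replicate 1 reads to a replicate 2 list made from replicate 2 alone would lower q-values at sites both share, but only 6.996% of the 243 regions in all 3 lists had a lower q-value in the combined list (upper bound 10.96%), which argues against it. A candidate explanation is that the file for replicate 2 was called on reads that include those of replicate 1, since 41 edges coincided to the base between the replicate lists, against at most 11 at any other offset up to 10 bp, though edges set by the genome sequence or by recurrent breakpoints stay open (5 pairs had both edges the same), and 6 replicate 1 regions missing from replicate 2, one of rank 71, are not what pooling would be expected to give. Also open, and untested, is that the combined file was called on replicate 2 reads alone, as 341 regions had the same coordinates and q-value in both lists. The 2 lists were not identical. The q-value was lower in the combined list at 34 regions and higher at 32, by up to 1.47 in −log10 q, and each list had 3 regions the other lacked. How much 2 calls on one set of reads and one control can differ was not tested. These differences therefore do not decide for or against either open reading.

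The second pattern is the excess of regions on X, for which no biological explanation was tested because the design has no group that bears on it. Counting closely spaced regions separately was argued against, since X held 26.4% of the loci left after joining regions within 10000 bp, with a lower bound of 21.9% above the 17.8% of length. Weak regions near the authors' threshold were argued against in the same way, since the share on X was 30.2% (interval 24.4 to 36.5) in the stronger 50% of the combined list. The number of protein-coding genes does not account for it either, since X carries 13.7% of them in the WBcel235 table. Differences between chromosomes in mappability, or in other kinds of gene such as tRNA genes, stay open and need a WS180 genome.

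The third pattern is the grouping of regions. If it came only from single broad sites split by gaps of at most 1000 bp, joining regions within 1000 bp would remove it, but 58 of the 439 loci left (13.2%) had another within 2000 bp, against 31 at most in random placements, and 142 had another within 10000 bp, against 73 at most. The share within 2000 bp was 23.4% before joining, so splitting is not excluded for part of the grouping. It was not limited to the lists that may hold pooled reads, since 36 replicate 1 regions had a neighbour within 2000 bp, against at most 18 in random placements. Gene-dense stretches with several regulatory sites are a possible explanation that was not tested.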
